A study of Homo sapiens with 54 samples.

How the data were processed

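Total RNA of leiomyosarcoma (LMS), a malignant tumour of smooth muscle cells, and of normal tissue was sequenced by the authors from cores of formalin-fixed, paraffin-embedded blocks. Per the labels, ribosomal RNA was depleted, libraries were primed at random and paired ends were read on an Illumina instrument. The deposited table held FPKM (fragments scaled by gene length and by the number of mapped fragments), which the authors computed with TopHat and Cufflinks on hg19. Their versions, options and gene annotation were not stated. The table had 1 column per case for 24 cases, although the labels listed 2 runs per case, 54 runs of 27 cases in all. How the runs of a case were joined was not stated. The labels named 9 cases of subtype I, 6 of subtype II, 5 of subtype III, 5 of normal smooth muscle, 1 of normal lung and 1 of normal skeletal muscle. Of these, 8, 6, 3, 5, 1 and 1 were in the table, and 3 cases (1 of subtype I and 2 of subtype III) were not analysed here. Columns were assigned to cases by the case name that the label and the column shared, and none was left over.

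The table named genes by symbol only. Of its 23970 entries, 28 bore a calendar date in place of a symbol and were excluded, because the symbol behind a date is ambiguous. Another 148 entries of sex-linked genes that reveal the sex of a donor were removed. FPKM was summed over 284 symbols that occurred more than once (628 entries), which left 23450 genes, 18799 of them protein-coding by the symbol in a GRCh38 annotation. That annotation was used for gene names and types alone, so no coordinates are given. The table held no read counts, so the depth in reads is unknown and no counting interval could be given. A relative depth was estimated from the steps between the lowest FPKM values of each case. It lay between 0.521 and 1.29 of the typical case. A median of 9.73% of the low values fell on the steps, and 90.6% of the 276 pairs of cases gave a ratio within 0.1 on the log2 scale of the ratio of the 2 estimates. Between 97.5% and 99.6% of the summed FPKM of a case came from 1727 small RNA genes, whose short length inflates FPKM. Of 194 genes with a median of at least 20 FPKM, 8 were listed at exactly 0 in at least 1 case, in 28 gene and case pairs. MALAT1 was listed at 0 in 10 cases, including all 5 of normal smooth muscle, and no fold change is given for it.

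Values were analysed as log2(FPKM + 1). Genes with at least 1 FPKM in at least 3 of the 22 fitted cases were kept, which left 13362. Fold changes on this scale understate the change of genes near or below 1 FPKM. A linear model with 1 mean per group was fitted to all 22 cases with limma 3.58.1 (R 4.3.3, statmod 1.5.0; lmFit, contrasts, eBayes with trend and robust options). The Benjamini-Hochberg adjusted p had to be below 0.05. The 7 contrasts were the 3 pairs of subtypes, each subtype against normal smooth muscle, and LMS against normal smooth muscle, where LMS was the unweighted mean of the 3 subtype means. Lung and skeletal muscle, with 1 case each, entered no test. The model was tested on simulated data with 50 changed genes at each of 4 sizes. It recovered 72% of the changes of 2 on the log2 scale between subtypes I and II, 56% between I and III, 60% between II and III and 84% between LMS and normal smooth muscle, and false calls made up 2.82% to 6.49% of its calls. In the simulation each gene had the same mean in all groups before the change, and independent normal noise with its residual SD. Changes were planted only in genes with a mean log2 value above 2. Shifts of whole cases and correlation between genes were not simulated, so these rates need not hold for the real data. No batch was named in the labels. The p-values rest on the spread between these cases within groups, taken as a residual variance per gene that all groups shared. The spread of a group that varied more than the others may therefore be understated.

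A set of 23 gene lists was written before the data were examined. So were the model, the filter, the pseudocount, the main list of alternative settings and the rule for named genes. The lists held 582 entries, 581 of them found in the table, and a gene could stand in several lists. One list, a panel of 35 LMS genes, was read gene by gene, and the other 22 were tested with camera (preset correlation of 0.01) against all other genes, with Benjamini-Hochberg adjustment over the 22 lists within each comparison. Camera with an estimated correlation and fry were run as alternatives. Beside the count of called members over all genes, the count adjusted over the list alone is given. The shift of a list is its mean log2 change minus the mean of all tested genes, and its score in a case is the mean log2(FPKM + 1) of its tested members minus the mean of all tested genes. The named genes of a comparison were the 12 highest and the 12 lowest log2 changes among called genes with a mean of at least 5 FPKM in the higher group, without small RNA genes, unnamed loci and immunoglobulin or T-cell receptor segments. To these were added up to 4 of the smallest p in each list that is described and any panel gene. The genes whose group means are given were chosen after the data were seen. The results of some named genes are not reported here.

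Separation of the subtypes was the mean of 1 minus Spearman's rho between cases of different subtypes minus the mean within subtypes, with a one-sided test by 100000 permutations of the subtype labels. Similarity to normal smooth muscle was the mean rho of an LMS case with the 5 normal cases, compared between subtypes by exact two-sided permutation tests with adjustment over the 3 pairs. The alternatives planned before the data were examined were a pseudocount of 0.1, no filter, a filter at 5 FPKM, quantile normalization, rescaling each case to a fixed total, a fit of the compared groups alone, array weights, insert size as a covariate, the highest entry for repeated symbols, and leaving out each case. Rescaling on protein-coding genes, treating the listed zeros as missing, and leaving out subtype III replicate 1 together with subtype I replicate 7 were added after seeing the data. Tables were handled with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.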

Results

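Leiomyosarcoma has been divided into molecular subtypes by gene expression, and the series profiled 3 of them beside normal tissue. The values analysed were FPKM of 24 cases, 1 column per case. There were 8 LMS cases of subtype I, 6 of subtype II, 3 of subtype III, 5 of normal smooth muscle, 1 of normal lung and 1 of normal skeletal muscle. Replicate numbers name cases, and each case is a biological replicate. Between 7664 and 11397 genes reached 1 FPKM in 23 of the cases, and 4132 did in subtype III replicate 1. The summed FPKM of protein-coding genes was 15948 in subtype III replicate 1 and 30889 in subtype III replicate 4, against 39220 to 87782 in the other cases. Because the summed FPKM of protein-coding genes differed between cases, the median log2 change of all genes is given for each comparison. Counts are also given after quantile normalization.

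**Figure D1:**
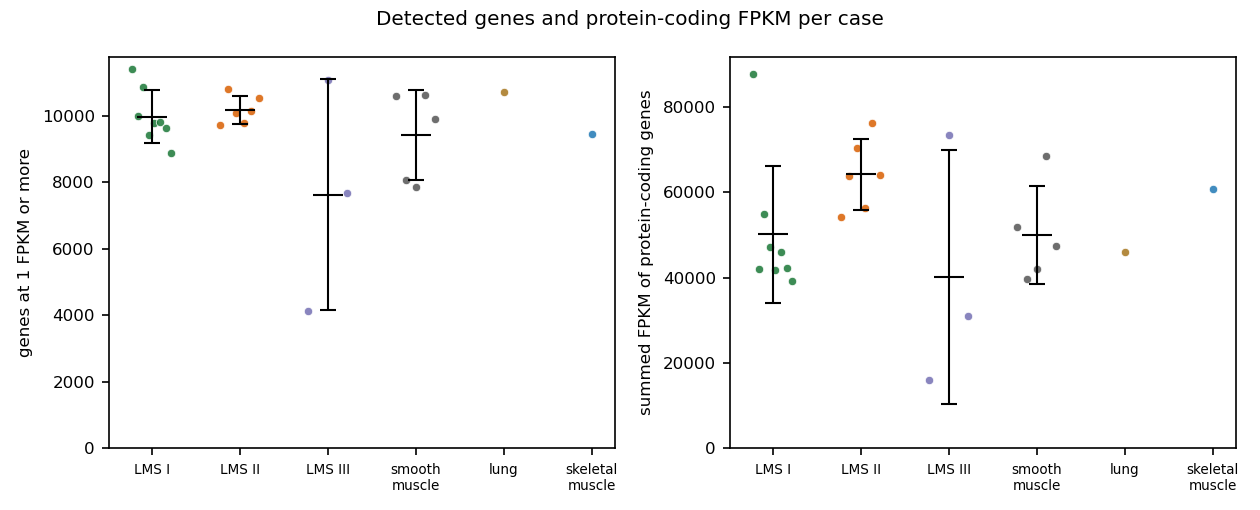
Genes at 1 FPKM or more (left) and summed FPKM of protein-coding genes (right) for each of the 24 cases by group; points are cases and bars are the mean and SD of groups with at least 3 cases. Subtype III replicate 1 had the lowest values of both, 4132 genes and 15948 FPKM.

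The comparison of subtypes I and II asked which transcripts set these tumours apart. Several smooth muscle genes were higher in subtype I. SYNPO2, which encodes an actin-binding protein of muscle, stood at 69.0 ± 43.2 FPKM (SD, n = 8) in subtype I and 6.55 ± 10.3 (n = 6) in subtype II. Its log2 change was 3.70 ± 0.73 (SE, adjusted p = 0.011). PPP1R12B, a regulatory subunit of myosin phosphatase, was higher by 3.18 ± 0.57 on the log2 scale (adjusted p = 0.0052), and MYOCD, the coactivator that switches on smooth muscle genes, by 2.33 ± 0.60 (adjusted p = 0.045). KCNMB1, a subunit of the smooth muscle calcium-activated potassium channel, was higher by 2.46 ± 0.43 (adjusted p = 0.0045). Other genes were higher in subtype II. The secreted matricellular protein gene WISP1 stood at 28.8 ± 30.8 FPKM in subtype II and 1.37 ± 0.88 in subtype I, a log2 change of −3.34 ± 0.42 (adjusted p = 3.0e-04). TENM3, a teneurin of the cell surface, changed by −2.60 ± 0.28 (adjusted p = 3.1e-05), and RUNX2, the transcription factor of bone-forming cells, by −2.70 ± 0.44 (adjusted p = 0.0038).

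In all, 288 of 13362 genes passed the test, 51 higher and 237 lower in subtype I, with a median log2 change of −0.15 over all genes. After quantile normalization the median was −0.01 and 295 genes passed, 139 higher and 156 lower, of which 177 were shared. Rescaling on protein-coding genes turned the balance to 369 higher and 135 lower, with a median of 0.10 and also 177 shared, so neither direction prevailed under all scalings. Without subtype III replicate 1 and subtype I replicate 7 the counts were 199 higher and 423 lower. Leaving out single cases gave between 92 genes (without subtype I replicate 8) and 425 (without subtype I replicate 7). JPH2, SVIL, MAOB, RASL12, CX3CL1, MRVI1 and TACC2 were also named by the rule as higher in subtype I, with log2 changes of 1.62 to 2.70. Named as lower in subtype I were MME, MMP2, GJA1, RND3, CLMP, PHLDA1, ANTXR1 and PCOLCE, with log2 changes of −2.97 to −2.36. Of the 24 named genes, WISP1, MME, GJA1, RUNX2, TENM3, CLMP and ANTXR1 were among the 8 that passed under every alternative in which they were tested. All 8 were lower in subtype I, and 0 of the 12 named as higher in subtype I passed under every alternative. SYNPO2, PPP1R12B and KCNMB1 each missed in 1 of 26, the rescaling to a fixed total, and MYOCD missed in 15 of 26.

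The smooth muscle contractile list was higher in subtype I. It had 39 of 42 members with a positive change, a shift of 1.78 against all genes and a camera adjusted p of 2.4e-18, but an adjusted p = 0.25 with an estimated correlation. Of its members 5 passed over all genes and 15 adjusted over the list alone. The extracellular matrix list was lower in subtype I, with a shift of −1.41 (adjusted p = 2.2e-10; adjusted p = 0.20 with an estimated correlation). Of 31 members, 7 passed and 17 did adjusted over the list alone, among them FAP (−1.91 ± 0.33), FBN1 (−2.14 ± 0.42) and COL5A1 (−2.02 ± 0.43), which encode a fibroblast protease, fibrillin and a collagen chain. Mesenchymal transcription factors were lower (shift −0.66, adjusted p = 0.013; adjusted p = 0.20 with an estimated correlation), with 3 of 14 members passing and 5 adjusted over the list alone, led by RUNX2, TCF4 (−1.43 ± 0.28) and SNAI2 (−2.02 ± 0.43). The interferon response list was higher in subtype I (shift 0.81, adjusted p = 2.2e-10; adjusted p = 0.20 with an estimated correlation), with MX1 (1.22 ± 0.33) passing over all genes and 7 of 23 members adjusted over the list alone.

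Immediate early genes were lower in subtype I than in subtype II (shift −0.87, adjusted p = 6.0e-06; adjusted p = 0.26 with an estimated correlation). SOCS3 (−1.54 ± 0.38) and MYC (−1.56 ± 0.41) passed over all genes, and 11 of 24 members did adjusted over the list alone. Ribosomal protein genes had a shift of −0.71 (adjusted p = 7.3e-07; adjusted p = 0.58 with an estimated correlation) and no member that passed either adjustment, the lowest p being that of RPL7 (adjusted p = 0.054). Hypoxia and glycolysis genes had a shift of −0.65 (adjusted p = 0.0032; adjusted p = 0.58 with an estimated correlation), with 0 of 19 members passing over all genes and 6 adjusted over the list alone. No member passed either adjustment in the 5 remaining lists called by camera. Of these, HLA class II (shift 0.51, adjusted p = 0.0098), sex steroid receptors and reproductive tract regulators (0.64, 0.013) and skeletal muscle (0.77, 0.015) were higher, and endothelial cells (−0.32, 0.013) and oxidative phosphorylation (−0.26, 0.040) were lower. With an estimated correlation, their adjusted p was 0.58, 0.58, 0.25, 0.70 and 0.89. The other 10 lists, proliferation and the markers of macrophages, T cells, B cells, adipocytes, epithelium, nerve and red blood cells, HOX genes and histones, did not pass (adjusted p of 0.077 to 0.93).

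Of the 35 panel genes, 3 passed over all genes (MYOCD and MYC among them) and 9 adjusted over the list alone. LMOD1, which encodes an actin nucleator of smooth muscle, stood at 33.6 ± 21.4 FPKM (SD, n = 8) in subtype I, 4.51 ± 8.24 (n = 6) in subtype II and 24.8 ± 23.2 (n = 3) in subtype III. Its log2 change between I and II was 3.06 ± 0.86 (adjusted p = 0.060 over all genes and 0.014 over the list alone). MYH11, the smooth muscle myosin heavy chain, differed by 4.75 (adjusted p = 0.063 over all genes and 0.010 over the list alone). LMOD1 is a known marker of subtype I, and the subtypes were defined by expression, so these differences are not independent evidence of the subtypes.

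**Figure D2:**
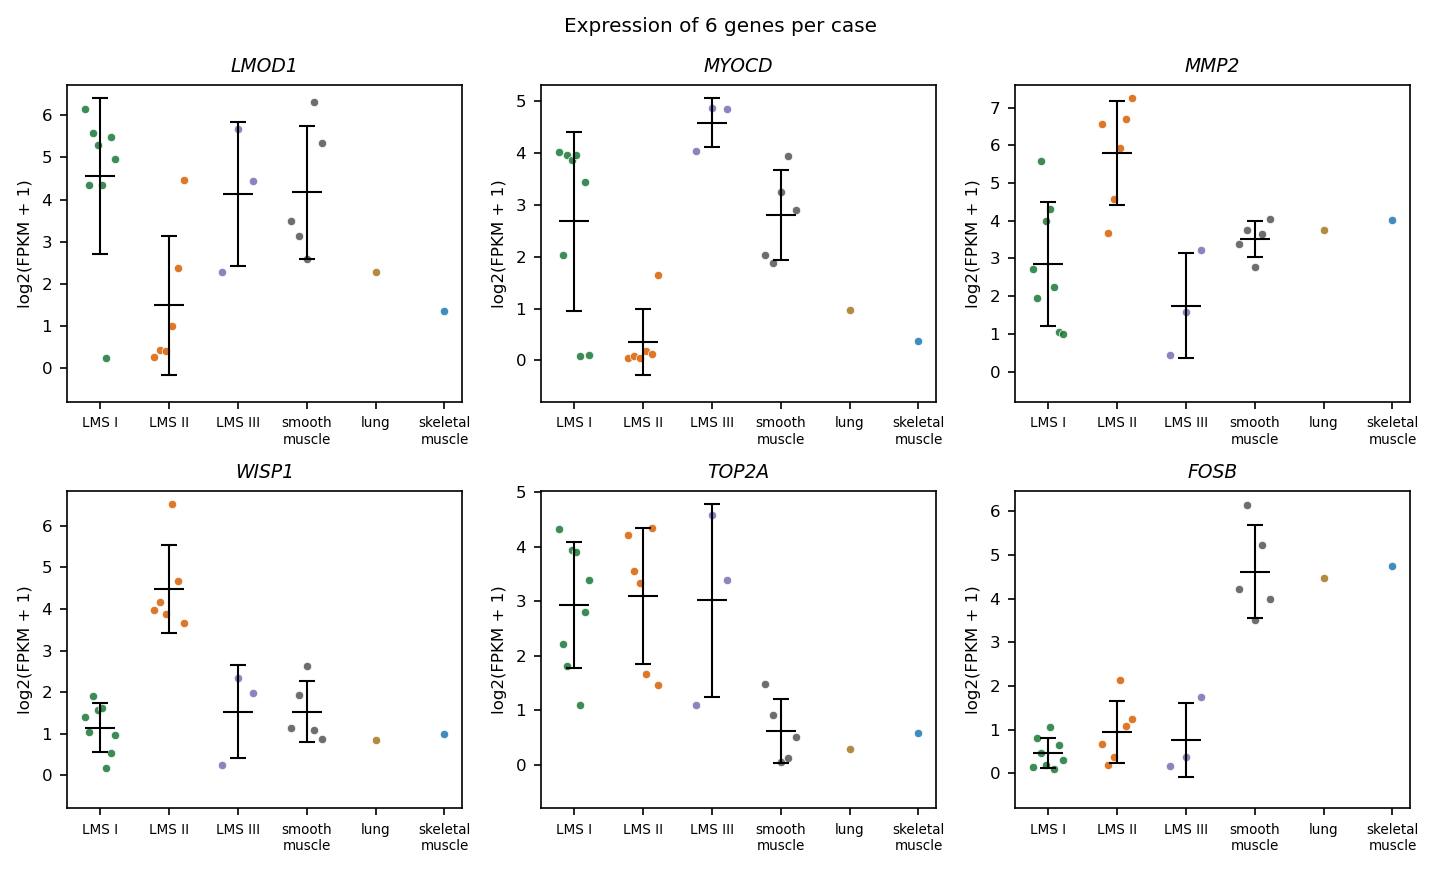
Expression of LMOD1, MYOCD, MMP2, WISP1, TOP2A and FOSB as log2(FPKM + 1) in each of the 24 cases by group; points are cases and bars are the mean and SD of groups with at least 3 cases. In subtype I replicate 7 LMOD1 was at 0.23, while the other subtype I cases lay between 4.34 and 6.16.

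Between subtypes I and III no gene passed the limma test (0 of 13362), while 1427 had an unadjusted p below 0.05. Among the gene lists, antigen presentation had the largest shift. CD74, the invariant chain of HLA class II, had a log2 change of 2.78 ± 0.75 (adjusted p = 0.29 over all genes) and HLA-DRB1, an HLA class II chain, of 2.82 ± 0.67 (adjusted p = 0.27). The HLA class II list had a shift of 1.31 above all genes (camera adjusted p = 4.5e-10; adjusted p = 0.51 with an estimated correlation), and 10 of its 12 members passed adjusted over the list alone. Macrophage genes were called higher in subtype I as well (shift 0.86, adjusted p = 6.8e-07; adjusted p = 0.66 with an estimated correlation), with 9 of 21 members passing adjusted over the list alone, led by the complement genes C1QA (1.98 ± 0.57) and C1QB (2.10 ± 0.61). The median log2 change of all genes was 0.29, and it was −0.003 after quantile normalization, which gave 1 called gene. Leaving out subtype III replicate 2 gave 779 genes and leaving out both doubtful cases gave 0, so a count of 0 is bound to which of the 3 cases are compared.

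In the other lists called between I and III, no member passed over all genes or adjusted over the list alone. Histone genes (shift 0.82, adjusted p = 0.012) and interferon response genes (0.37, 0.0033) were called higher in subtype I, but not with an estimated correlation (adjusted p of 0.85 and 0.75). Proliferation (−0.25, 5.3e-04), nerve (−0.47, 0.0029), sex steroid (−0.47, 0.0040), immediate early (−0.18, 0.028) and skeletal muscle genes (−0.30, 0.048) were called lower, but not with it (adjusted p of 0.85, 0.66, 0.72, 0.85 and 0.66). With an estimated correlation the adjusted p of all 9 called lists lay between 0.51 and 0.85. The median log2 change was above 0 for proliferation (0.02), immediate early (0.15) and skeletal muscle genes (0.20), but below the median of 0.29 over all genes. Changes of genes near or below 1 FPKM are understated on this scale, so an effect of low expression was not told apart. The test compares a list with all other genes, so these lists were lower only relative to them. The remaining 13 lists, smooth muscle and extracellular matrix among them, did not pass (adjusted p of 0.079 to 0.93). No panel gene passed, and LMOD1 differed by 0.42 ± 1.08.

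Between subtypes II and III, COL3A1, a fibrillar collagen chain, had a log2 change of 4.75 ± 1.04 (adjusted p = 0.030), but it was listed at 0 in subtype III replicate 2, and with that entry missing the change was 3.03 (adjusted p = 0.10). MMP2, which degrades collagens, stood at 73.9 ± 53.1 FPKM (SD, n = 6) in subtype II and 3.54 ± 4.18 (n = 3) in subtype III, a log2 change of 4.04 ± 0.88 (adjusted p = 0.031). PDGFRB, a growth factor receptor of mural and stromal cells, stood at 20.1 ± 15.2 FPKM against 1.40 ± 0.88 (2.99 ± 0.55, adjusted p = 0.013). MYOCD went the other way, with 0.41 ± 0.84 FPKM in subtype II and 23.8 ± 7.24 in subtype III (−4.23 ± 0.79, adjusted p = 0.015), and so did PPP1R12B (−3.70 ± 0.75, adjusted p = 0.020).

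Of 13362 genes, 114 passed, 110 higher and 4 lower in subtype II, with a median log2 change of 0.43 over all genes. After quantile normalization the median was 0.01 and 28 were higher and 44 lower, with 32 genes shared, so the direction of the bulk followed the scaling. The other genes that the rule named as higher in subtype II were TGFBI, SDCBP, CTHRC1, WISP1, CLMP, FBN1, RUNX2, COL5A2 and EMP1, with log2 changes of 2.69 to 3.82. LONRF2 was the last of the 3 named as lower, with a change of −2.01. None of these 15 named genes passed under every alternative. The count was 13 without subtype III replicate 1, 9 without replicate 4 and 4194 without replicate 2. It was 18 without subtype III replicate 1 and subtype I replicate 7.

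The extracellular matrix list was higher in subtype II (shift 1.92, camera adjusted p = 2.0e-10; adjusted p = 0.17 with an estimated correlation). Of its 31 members 9 passed and 26 did adjusted over the list alone, with FAP at 2.55 ± 0.43 and FBN1 at 2.78 ± 0.55. Mesenchymal transcription factors were higher (shift 0.90, adjusted p = 0.0051; adjusted p = 0.17 with an estimated correlation), with 3 of 14 members passing and 6 adjusted over the list alone; TCF4 was at 2.63 ± 0.36 (adjusted p = 0.0011). The smooth muscle list was lower in subtype II (shift −1.72, adjusted p = 5.5e-24; adjusted p = 0.17 with an estimated correlation), with 2 of 42 members passing and 4 adjusted over the list alone. Macrophage (shift 0.92, adjusted p = 8.4e-05), endothelial (0.56, 2.3e-04), HLA class II (0.80, 0.0070), hypoxia (1.01, 3.6e-04) and ribosomal genes (0.93, 2.5e-06) were called higher in subtype II, each with an adjusted p = 0.43 with an estimated correlation. No member of these 5 lists passed over all genes, and 14, 13, 8, 6 and 19 did adjusted over the list alone. The macrophage shift leaned on subtype II replicate 4, which had a score of 2.12. The other subtype II cases lay between −0.69 and 0.36, and subtype III between −0.72 and −0.47. LAPTM5, a lysosomal protein of blood cells, had a log2 change of 2.36 ± 0.61 and ENG, a receptor of endothelial cells, of 1.45 ± 0.43.

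Immediate early (shift 0.69, adjusted p = 0.015) and histone genes (0.95, 0.042) were called higher in subtype II, but not with an estimated correlation (adjusted p of 0.43 and 0.67), with 8 and 0 members passing adjusted over the list alone. Sex steroid (−1.11, 2.0e-06), skeletal muscle (−1.07, 6.6e-05), interferon (−0.44, 5.6e-04), nerve (−0.39, 0.0053), HOX (−0.33, 0.012), epithelial (−0.46, 0.020) and adipocyte genes (−0.45, 0.030) were called lower, but not with an estimated correlation (adjusted p of 0.18, 0.076, 0.43, 0.43, 0.43, 0.43 and 0.43). No member of these 9 lists passed over all genes, and adjusted over the list alone 1 skeletal muscle gene was the only one among those lower. With an estimated correlation the adjusted p of the 17 called lists lay between 0.076 and 0.67. The medians of nerve (0.02), HOX (0.07), epithelial (0.04) and adipocyte genes (0.08) lay above 0 but below the median of 0.43 over all genes. Their mean scores lay below 0 in both subtypes, and changes of genes near or below 1 FPKM are understated on this scale. An effect of low expression was therefore not told apart from a difference between the subtypes. The test compares a list with all other genes, so these lists were lower only relative to them. The remaining 5 lists did not pass (adjusted p of 0.077 to 0.86). Of the 35 panel genes 3 passed, PDGFRB and MYOCD among them, and 10 did adjusted over the list alone.

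**Figure D3:**
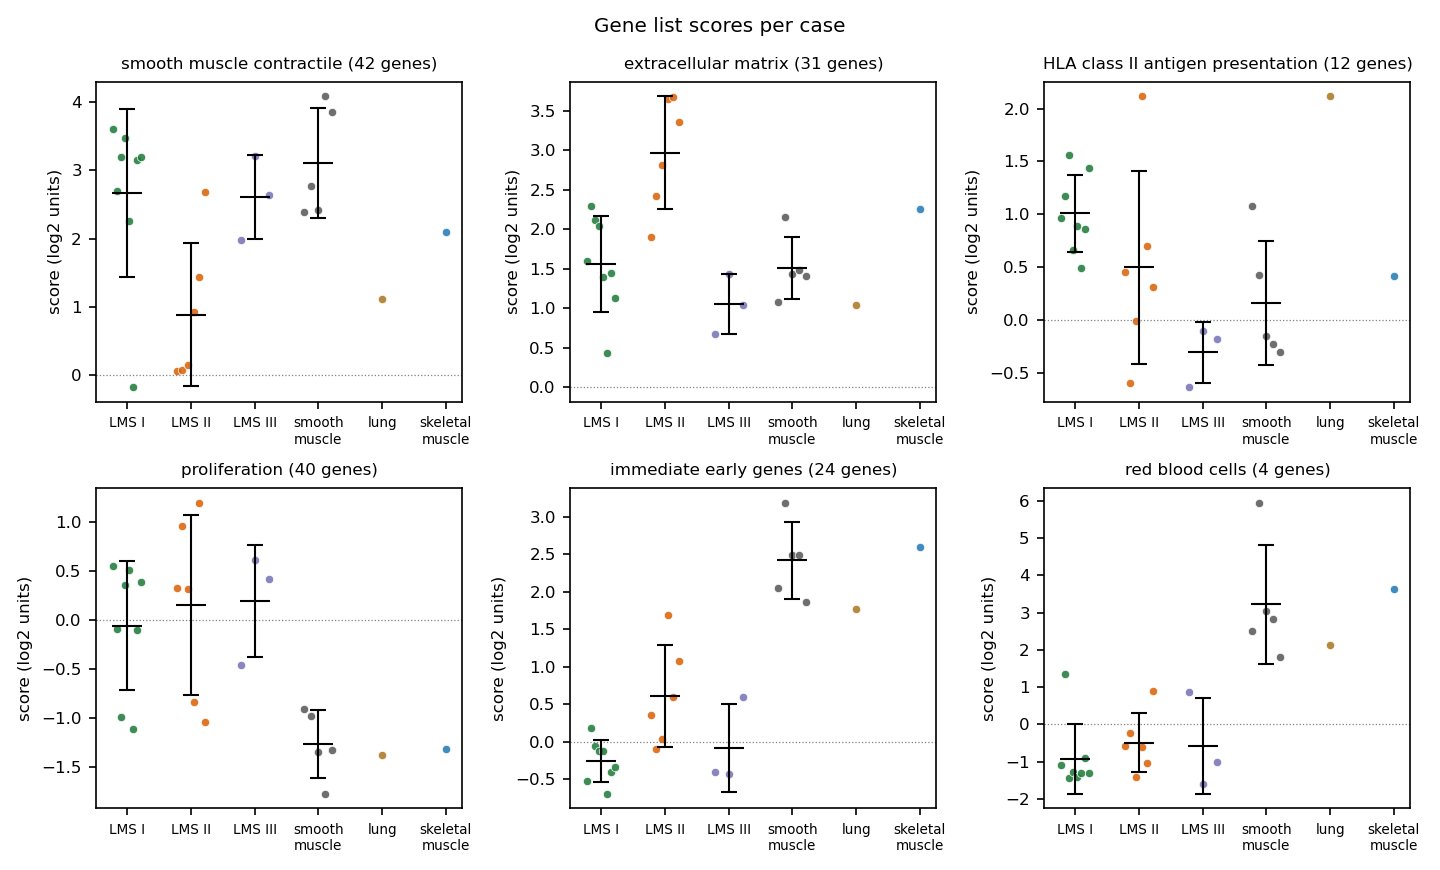
Scores of 6 gene lists in each of the 24 cases by group, in log2 units relative to the mean of all 13362 tested genes of the case; points are cases and bars are the mean and SD of groups with at least 3 cases. The 5 normal smooth muscle cases had immediate early gene scores of 1.87 to 3.19, and the highest LMS score was 1.69.

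Over all genes the LMS cases differed more between subtypes than within them. The mean distance (1 minus Spearman's rho) was 0.362 between and 0.316 within subtypes, a difference of 0.0459 (one-sided permutation p = 7.2e-04, 17 cases). Because the subtypes were defined by expression, a separation in expression is partly built in, and this p is not independent evidence of it. Leaving out single cases kept the difference between 0.0372 and 0.0606. The mean rho with normal smooth muscle was 0.610 ± 0.0545 (SD, n = 8) for subtype I, 0.626 ± 0.0573 (n = 6) for II and 0.592 ± 0.0166 (n = 3) for III, against 0.755 ± 0.0146 (n = 5) among the normal cases themselves. No pair of subtypes differed beyond the spread between cases, with differences of −0.0158, 0.0185 and 0.0343 (exact two-sided permutation p of 0.60, 0.62 and 0.43, adjusted p = 0.62 for each). The smooth muscle score was 2.67 ± 1.23 in subtype I, 0.889 ± 1.04 in II and 2.61 ± 0.617 in III.

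The comparison of LMS with normal smooth muscle asked which transcripts differ between the tumours and normal tissue. Among cell division genes, 16 of the 40 of the proliferation list were higher in LMS, although the list as a whole was not called with an estimated correlation (adjusted p = 0.20). TOP2A, the topoisomerase of dividing cells, stood at 8.80 ± 6.54, 10.1 ± 7.45 and 11.1 ± 10.96 FPKM (SD, n = 8, 6 and 3) in subtypes I, II and III and at 0.643 ± 0.719 (n = 5) in normal smooth muscle, a log2 change of 2.40 ± 0.56 (SE, adjusted p = 0.018). CDKN2A, a cell cycle inhibitor, was higher by 2.00 ± 0.35 (adjusted p = 0.0016), from 0.0796 ± 0.0394 FPKM in normal smooth muscle to 5.001 ± 5.24 in subtype I. Immediate early genes, which respond within minutes to stimulation, were lower in LMS. FOSB, a subunit of the AP-1 transcription factor, stood at 29.7 ± 24.5 FPKM in normal smooth muscle and at 0.415 ± 0.358, 1.15 ± 1.19 and 0.921 ± 1.23 in subtypes I, II and III, a log2 change of −3.89 ± 0.35 (adjusted p = 5.6e-07). The haemoglobin gene HBB, a marker of red blood cells, was at 318.8 ± 525.2 FPKM in normal smooth muscle and at 4.29 ± 7.32, 8.66 ± 13.0 and 1.88 ± 1.51 in subtypes I, II and III (−4.97 ± 0.76, adjusted p = 7.4e-04).

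Of 13362 genes, 505 passed, 115 higher and 390 lower in LMS, with a median log2 change of 0.06. After quantile normalization 1247 passed, 544 higher and 703 lower, with 497 shared and a median of 0.05. The mean insert size was 139.8 ± 4.97 bases (SD, n = 5) in normal smooth muscle and 147.5 ± 5.59 (n = 8), 144.7 ± 5.85 (n = 6) and 146.5 ± 12.3 (n = 3) in subtypes I, II and III, and with it as a covariate 306 genes passed, 22 higher and 284 lower. Leaving out the 2 doubtful cases gave 476 higher and 376 lower. The count was 280 (17 higher) without normal smooth muscle replicate 3 and 301 (35 higher) without replicate 2. Without normal replicates 1, 4 and 5 there were 67, 46 and 49 higher, and leaving out single LMS cases gave 68 (without subtype III replicate 4) to 383 higher (without subtype III replicate 1). Rescaling to a fixed total, with 4874 genes tested, gave 28 higher and 1991 lower. The other genes named by the rule as higher in LMS were HIST1H2AG, HIST1H2AM, HIST2H3C, CENPF, ANLN, TERC, CDKN2C, NUSAP1, STMN1, MMP14 and UBE2C, with log2 changes of 1.96 to 2.48. Those lower in LMS were HBA1, HBA2, DES, FOS, ZFP36, BTG2, PIGR, EGR1, NR4A1 and SOCS3, with log2 changes of −4.27 to −3.49. DES, the intermediate filament protein of muscle, stood at 289.2 ± 308.0 FPKM in normal smooth muscle and 47.7 ± 68.0 in subtype I (log2 change against LMS −4.12 ± 1.03, adjusted p = 0.028). All 12 genes named as lower except DES and PIGR passed under each of the 33 alternatives. None of the 12 named as higher did.

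The proliferation list was higher in LMS (shift 1.37, camera adjusted p = 7.7e-25; adjusted p = 0.20 with an estimated correlation). All 40 members had a positive change, 16 passed and 39 did adjusted over the list alone, among them NUSAP1 (2.11 ± 0.48), CDK1 (1.88 ± 0.45) and TYMS (1.81 ± 0.44), which act in the spindle, the cell cycle and nucleotide synthesis. Histone genes were higher too (shift 1.17, adjusted p = 1.1e-06; adjusted p = 0.54 with an estimated correlation), with 2 of 23 passing and 6 adjusted over the list alone. Immediate early genes were lower (shift −2.33, adjusted p = 2.7e-34; adjusted p = 0.0023 with an estimated correlation). Of 24 members 18 passed and 22 did adjusted over the list alone, with NR4A1, a nuclear receptor, at −3.54 ± 0.32 and ZFP36, an RNA-binding protein that destabilises messages, at −3.63 ± 0.41. In the normal lung FOSB stood at 21.2 FPKM and in the skeletal muscle at 25.96.

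Markers of other cell types were lower in LMS beside these genes, but some differed widely between the normal cores. The epithelial score ranged from −1.74 to 2.35 in normal smooth muscle, with means of −1.38, −1.63 and −1.17 in subtypes I, II and III. That of B and plasma cells ranged from −1.54 to 3.42, with subtype means of −1.07, −1.20 and −0.65. That of red blood cells was at least 1.81 in normal smooth muscle and at most 1.36 in LMS. Red blood cell genes had a shift of −3.89 (4 of 4 members passing, also adjusted over the list alone; adjusted p = 8.2e-09, and adjusted p = 0.0028 with an estimated correlation). Nerve and Schwann cell genes had a shift of −0.74 (7 of 13 passing and 8 adjusted over the list alone; adjusted p = 8.2e-09, and adjusted p = 0.079 with an estimated correlation), led by CDH19 (−1.95 ± 0.25) and S100B (−1.59 ± 0.25). Epithelial genes had a shift of −1.22 (1 of 7 passing and 5 adjusted over the list alone; adjusted p = 3.2e-05, and adjusted p = 0.27 with an estimated correlation) and adipocyte genes of −0.82 (2 of 8 passing and 4 adjusted over the list alone; adjusted p = 2.2e-04, and adjusted p = 0.18 with an estimated correlation). The smooth muscle list was also lower in LMS (shift −1.05, adjusted p = 1.0e-06, and adjusted p = 0.61 with an estimated correlation). SYNM, TNS1 and DES passed among 42 members, and 7 did adjusted over the list alone. The shift came mostly from subtype II. The mean score was 3.11 in normal smooth muscle, 2.67 in subtype I, 0.889 in II and 2.61 in III. B and plasma cell genes had a shift of −1.87 that was not called (adjusted p = 0.071; adjusted p = 0.34 with an estimated correlation), but IGJ, 1 of the 2 members, was lower (−3.49 ± 0.90, adjusted p = 0.036), at 101.9 ± 181.9 FPKM in normal smooth muscle. In all, 14 lists did not pass (adjusted p of 0.063 to 0.84), B and plasma cell, matrix, macrophage, endothelial and T cell genes among them. Of the 35 panel genes, CDKN2A was higher and KIT (−1.29), MYC (−1.51) and CSF1 (−0.95) were lower, 4 in all and 5 adjusted over the list alone.

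Some smooth muscle transcripts were lower in subtype II than in normal smooth muscle. SYNPO2 changed by −4.30 and SYNM by −3.90 on the log2 scale, and the list had a shift of −2.22 with 10 of 42 members passing and 22 adjusted over the list alone (camera adjusted p = 1.4e-21; adjusted p = 0.16 with an estimated correlation). Matrix genes were higher in subtype II (shift 1.46, adjusted p = 2.1e-07; adjusted p = 0.16 with an estimated correlation), with 13 of 31 members passing and 20 adjusted over the list alone, among them MMP14 (3.41) and CTHRC1 (3.33). Mesenchymal transcription factors were higher (shift 0.73, adjusted p = 0.033; adjusted p = 0.16 with an estimated correlation), with 4 of 14 passing by both adjustments, SNAI2 (2.58) and TWIST1 (2.41) among them. Proliferation genes were higher, with 27 of 40 members passing and 39 adjusted over the list alone (adjusted p = 6.0e-17; adjusted p = 0.20 with an estimated correlation). CDKN2A (2.32), CD276 (1.81), PDGFRB (1.83) and MYOCD (−2.45) were among the panel genes that passed, 5 over all genes and 6 adjusted over the list alone. Immediate early genes were lower (shift −1.81, adjusted p = 1.4e-21; adjusted p = 0.012 with an estimated correlation), with 12 of 24 members passing and 14 adjusted over the list alone. Nerve (shift −0.84, adjusted p = 1.8e-09), adipocyte (−1.11, 1.2e-05) and epithelial genes (−1.45, 4.6e-06) were called lower too, but not with an estimated correlation (adjusted p of 0.062, 0.081 and 0.16); 8 of 13, 3 of 8 and 1 of 7 members were lower over all genes, and 8, 4 and 3 adjusted over the list alone. B and plasma cell (shift −2.10, adjusted p = 0.032) and skeletal muscle genes (−0.51, 0.045) were called lower and histone (1.53, 4.6e-06) and ribosomal genes (0.71, 7.8e-05) higher, but not with an estimated correlation (adjusted p of 0.17, 0.20, 0.41 and 0.61); 0 of 2, 1 of 6, 3 of 23 and 1 of 44 members passed over all genes, and 1, 1, 17 and 1 adjusted over the list alone. The comparison gave 832 genes, 573 higher and 259 lower, and 422 higher and 504 lower after quantile normalization, where 616 were shared; the median log2 change was 0.23, and 0.03 after it. Leaving out subtype II replicate 5 gave 297 genes.

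Subtype I against normal smooth muscle gave 317 genes, 84 higher and 233 lower, with a median log2 change of 0.11. After quantile normalization it gave 353 higher and 560 lower, 314 of them shared, and after rescaling on protein-coding genes 513 higher and 409 lower, 311 of them shared. CDKN2A was higher by 2.14 ± 0.38, MYC lower by a log2 change of −2.04 ± 0.43 and KIT by −1.62 ± 0.37, 3 of the panel genes over all genes and 4 adjusted over the list alone. Immediate early genes were lower (shift −2.68, adjusted p = 6.2e-41; adjusted p = 8.3e-04 with an estimated correlation), with 18 of 24 members passing and 22 adjusted over the list alone. Nerve and Schwann cell genes were also lower (shift −0.92, adjusted p = 4.3e-10; adjusted p = 0.047 with an estimated correlation), with 7 of 13 passing and 8 adjusted over the list alone. Epithelial (shift −1.21, adjusted p = 5.9e-05) and adipocyte genes (−0.70, 0.0019) were called lower, each with an adjusted p = 0.34 with an estimated correlation; 0 of 7 and 2 of 8 members passed over all genes, and 4 and 2 adjusted over the list alone. Proliferation genes were called higher (shift 1.21, adjusted p = 3.2e-17; adjusted p = 0.34 with an estimated correlation), with 2 of 40 passing and 35 adjusted over the list alone. Histone genes were called higher as well (shift 1.39, adjusted p = 1.3e-07; adjusted p = 0.37 with an estimated correlation), with 0 of 23 passing and 11 adjusted over the list alone. Interferon response genes were higher (shift 0.58, adjusted p = 1.2e-04; adjusted p = 0.37 with an estimated correlation), with CXCL9, a chemokine that interferon induces, passing and 8 of 23 adjusted over the list alone. HLA class II genes were higher (shift 0.84, adjusted p = 2.9e-04; adjusted p = 0.37 with an estimated correlation), with 0 of 12 passing and 7 adjusted over the list alone. The smooth muscle list was called lower by a shift of −0.43 with no member passing either adjustment (adjusted p = 0.028; adjusted p = 0.86 with an estimated correlation), and the call was lost without subtype I replicate 7 (adjusted p = 0.73) or 6 (0.055), without normal smooth muscle replicate 4 (0.20) or 5 (0.18), and after quantile normalization (0.18).

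Subtype III against normal smooth muscle gave 164 genes, 4 higher and 160 lower, with a median log2 change of −0.19. After quantile normalization the median was 0.04 and 265 were higher and 257 lower, 147 of them shared; rescaling on protein-coding genes gave 308 higher and 236 lower. Immediate early genes were lower (shift −2.50, adjusted p = 6.3e-27; adjusted p = 0.0079 with an estimated correlation), with 15 of 24 members passing and 21 adjusted over the list alone. CSF1, a growth factor of macrophages, changed by −1.76 ± 0.37 (adjusted p = 0.018), the 1 panel gene that passed beside 8 adjusted over the list alone, and TCF4 by −1.97 (adjusted p = 0.011). Proliferation genes had a shift of 1.46 (adjusted p = 2.7e-26; adjusted p = 0.30 with an estimated correlation) and no member that passed either adjustment. Nerve genes were called lower (shift −0.45, adjusted p = 5.9e-04; adjusted p = 0.41 with an estimated correlation), with 3 of 13 passing and 6 adjusted over the list alone. Endothelial (shift −0.46, adjusted p = 0.010), adipocyte (−0.66, 0.022) and epithelial genes (−0.99, 0.022) were called lower and sex steroid (1.11, 1.9e-04) and histone genes (0.58, 0.0068) higher, but not with an estimated correlation (adjusted p of 0.70, 0.52, 0.68, 0.41 and 0.77). No member of these 5 lists passed over all genes, and 4 adipocyte genes did adjusted over the list alone. The count was 34 without subtype III replicate 4, 45 without replicate 1 and 1006 without replicate 2. Red blood cell genes were lower in every subtype against normal smooth muscle, with adjusted p of 0.0020, 0.0092 and 0.023 for subtypes I, II and III with an estimated correlation.

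**Figure D4:**
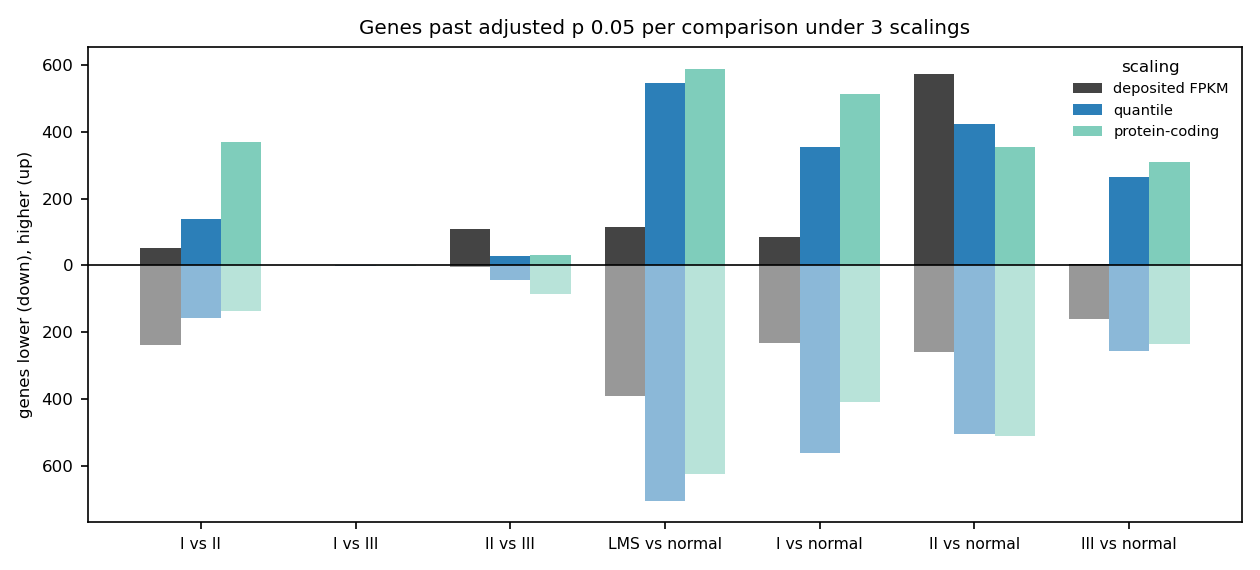
Number of genes past an adjusted p of 0.05 in each of the 7 comparisons, higher above the 0 line and lower below it, with the deposited FPKM, after quantile normalization and after rescaling on protein-coding genes. Between subtypes II and III the deposited FPKM gave 110 higher and 4 lower, and quantile normalization gave 28 higher and 44 lower.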

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

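The tests of low detection in subtype III replicate 1 and of few detected genes in subtype I replicate 7, the comparison of that case with held-out subtype II cases, the regroupings of cases, and the choice of genes examined for cases that stand apart were chosen only after the results were seen. The count behind the test on protein-coding genes had been seen too, but not its leave-one-out counts.

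Immediate early genes were lower in LMS than in normal smooth muscle. After quantile normalization the list's shift was −2.49 against −2.33 before it, which met the bound written against scaling of the FPKM as the cause. That test is weak and was not taken as deciding. The median log2 change of all genes was 0.06 before and 0.05 after it, so there was little common scaling difference to remove. In a shift taken against the mean of all genes, a common factor per case cancels only in part, because the added pseudocount holds low values near 0. A state or handling shared by normal tissue cores, such as the time from surgery to fixation, may account for part of the list's change. The normal lung and skeletal muscle cases, 1 each, both scored above the highest LMS case, but the lung by only 0.085. RNA of other cell types in the normal cores stays open. Normal smooth muscle replicate 4 had the lowest mean of the red blood cell, epithelial and nerve scores among the normal cases. For immediate early genes it still scored 0.809 above the highest LMS case, more than the LMS SD of 0.623. The prediction had set such a difference as counting against this cause. That bound was not taken as deciding, since it rests on 1 library. Also, 0 of the 5 normal cases had a mean of these 3 scores within the LMS range (0.298 to 1.495 against at most −0.04). Taken singly, the epithelial and nerve scores of normal and LMS cases overlapped, and only the red blood cell score kept them apart. A difference between tumour and normal tissue is untested beside these causes.

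The count of genes between subtypes II and III ran from 9 to 4194 when single cases were left out. Whether low detection in subtype III replicate 1 alone was behind this stays open: leaving out replicate 2 gave 4194 genes and leaving out replicate 4 gave 9, but the former leaves together replicates 1 and 4, which both had less protein-coding FPKM (15948 and 30889) than every other case. The summed FPKM of protein-coding genes is a candidate cause. After rescaling on these genes the highest count was 668 and the lowest 21, against 118 with all cases. Part of the spread was left after that rescaling, and with 3 cases of subtype III a biological difference among them could not be tested.

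Subtype I replicate 7 lacked smooth muscle transcripts: its smooth muscle score was −0.18, while the other subtype I cases lay between 2.26 and 3.61. LMOD1 (0.23 against 4.34 to 6.16) and SYNPO2 (2.38 against 5.48 to 7.05) were low on the log2 scale. STMN1, named as higher in LMS than in normal smooth muscle, was also low in this case (1.90 against 3.54 to 4.78). A library with few detected genes is argued against by its 8875 protein-coding genes, inside the range of 8261 to 10537 of the other subtype I cases, and a core dominated by another listed cell type by 0 of 9 such scores standing above the other LMS cases. Whether replicate 7 was a subtype II case under a subtype I label stays open. One result runs against it, over genes called higher in subtype II without replicate 7 and without a held-out subtype II case. There replicate 7 scored below each of the 6 held-out cases by 0.340 to 0.908 (their SD was 0.211). Other values run toward a subtype II case. Over these genes replicate 7 scored above every other subtype I case in 3 of the 6 sets. Over genes higher in subtype I it scored −1.09 to −0.80, and the held-out subtype II cases scored −1.31 to 0.19. The other subtype I cases scored at least 0.598 there, but they had served to choose both sets of genes. In the planned test, r with the subtype II mean (0.0698) exceeded r with the subtype I mean (−0.0283) by 0.0981. That was under the 0.1 set for it, so the planned test was undecided. A tumour of subtype I that has lost its smooth muscle program may also explain the low smooth muscle score, which was not tested.

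In all, 138 tests of single measures were run within subtype I (8 cases), subtype II (6) and normal smooth muscle (5). Subtype III, with 3 cases, was left out. In 18 tests a case lay far from the others, where chance marks about 1 in 20 independent tests. The measures overlap and reuse the same cases, and some genes were picked after the results were seen, so that rate is no fair yardstick. Subtype II replicate 4 had macrophage (2.12 against −0.69 to 0.36), B and plasma cell (0.789 against −1.79 to −1.43) and interferon scores (0.0717 against −0.75 to −0.53) above the other subtype II cases, and WISP1 at 6.52 against 3.66 to 4.66. Subtype II replicate 6 stood above its group in MYOCD (1.65 against 0.04 to 0.17), PPP1R12B (4.82 against 1.83 to 2.23) and the sex steroid score (0.55 against −1.60 to −0.97). Subtype I replicate 7 also had the highest HOX score of its group (0.0526 against −1.49 to −0.82). Subtype I replicate 2 stood above its group in the red blood cell score (1.36 against −1.43 to −0.90). Subtype I replicate 1 had a summed protein-coding FPKM of 87780 against 39220 to 54860. Among normal smooth muscle cases, replicate 2 had a nerve score of −1.13 (others −0.37 to −0.21), replicate 3 an interferon score of 0.33 (others −0.63 to −0.36), replicate 1 RUNX2 at 1.78 (others 0.49 to 0.77) and replicate 4 EGR1 at 7.08 (others 5.43 to 5.78).

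The lung and skeletal muscle cases entered no test, and some of their scores lay above all 22 fitted cases. The skeletal muscle case scored 4.84 for skeletal muscle genes (highest fitted case −0.12), 0.92 for adipocyte genes (0.53) and 1.87 for oxidative phosphorylation genes (1.75). The lung case scored 1.10 for T and NK cell genes (0.31), 0.90 for endothelial genes (0.62) and 0.80 for adipocyte genes (0.53).

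Regrouping the same cases at random argued against chance for the counts of LMS, subtype I and subtype II against normal smooth muscle, without excluding it. With 100 splits, the real one included, 1 of 100 was the smallest share possible, and it was not adjusted over the 7 comparisons. One split of 100, the real one, gave as many genes for LMS against normal smooth muscle (1 of 100; 505 against 18), subtype I against normal smooth muscle (1 of 100; 317 against 10) and subtype II against it (1 of 100; 832 against 38). For subtype III against it 2 of 56 splits did, a share under 0.05 that was also not adjusted over the 7 comparisons. Another split gave 279 against the real 164, so chance is less firmly argued against there. Between subtypes, random splits are a weak yardstick, because labels defined by expression tend to give more genes than random ones by construction. There, 1 of 100 splits gave as many genes for subtype I against II (288 against at most 15) and 4 of 84 for subtype II against III (114). Exchanging subtype II replicate 4 and subtype III replicate 2 gave 2052 for the latter, which points to a structure of the samples. That exchange groups subtype III replicates 1 and 4, the cases of lowest protein-coding FPKM, without replicate 2, and no split was run after rescaling, so a structure apart from this scaling was not tested. For subtype I against III the real count was 0, which any of the 100 splits must reach, so the comparison says nothing about chance; the highest split gave 741.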

How the results depend on the processing

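Rescaling on protein-coding genes and leaving out subtype III replicate 1 with subtype I replicate 7 were chosen only after the data were seen. No paired analysis was possible because replicate numbers only name cases. No depth in reads was known, so no detection limit could be given. The separation of subtypes passed in each setting run for it (Pearson's r, the 2000 most variable genes, the filter at 5 FPKM and single cases left out; lowest 0.0236, highest 0.0650). No similarity difference passed in these settings, and that of subtype I minus II turned from −0.0158 to 0.00343 with the stricter filter. Of the called genes whose settings were followed, 10 of 35 (I and II), 0 of 21 (II and III) and 27 of 65 (LMS and normal) passed under every alternative, and none reversed. A fit of the groups compared alone gives nothing for LMS and normal that the fit to all does not. The cause of the changes below was not tested, except that rescaling to a fixed total is governed by small RNA genes and that fewer cases or genes enter some fits.

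Comparisons are taken in the order I and II, I and III, II and III, LMS and normal, I and normal, II and normal, III and normal. The counts were 288, 0, 114, 505, 317, 832 and 164. A pseudocount of 0.1 moved II and III to 565 and III and normal to 455. No filter moved I and II to 119 and II and III to 60. The filter at 5 FPKM gave 231 for II and III and 166, 112, 402 and 69 for the 4 with normal tissue. Quantile normalization gave 1 for I and III, 72 for II and III, and 1247 for LMS, 913 for I and 522 for III against normal. Rescaling to a fixed total gave 12 for I and II, 1 for II and III, and 2019, 1961, 1270 and 962 against normal. Rescaling on protein-coding genes gave 504 for I and II, 1 for I and III, and 1212 for LMS, 922 for I and 544 for III against normal. Array weights gave 1381, 7031, 7960, 2555, 1266, 2559 and 7350; subtype III replicate 4 took a weight of 116.8, the others at most 3.32. Insert size as a covariate gave 758 for I and II, 703 for II and III, and 306 for LMS, 168 for I and 303 for II against normal. The compared groups alone gave 2 for II and III and 28 for III and normal. Without the 2 doubtful cases, the counts were 622 for I and II, 18 for II and III, and 852, 547, 1337 and 52 against normal.

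Leaving out single cases gave 92 to 425 for I and II, 0 to 779 for I and III, 9 to 4194 for II and III, 280 to 718 for LMS, 176 to 426 for I, 297 to 974 for II and 34 to 1006 for III against normal. Moves beyond 1.5 times came without subtype I replicates 2 (144), 6 (191), 8 (92) and 9 (112) and II replicates 2 (178), 3 (114), 4 (181) and 5 (115) for I and II. They came without III replicate 2 (779) for I and III, and without II replicates 1 (276), 3 (75), 5 (61) and III replicates 1 (13), 2 (4194) and 4 (9) for II and III. Against normal they came for LMS without normal replicates 2 (301) and 3 (280); for I without I replicate 8 (187) and normal 2 (206) and 3 (176). For II they came without II replicates 2 (449), 3 (379), 5 (297) and normal 2 (370), 3 (317) and 5 (385), and for III without III replicates 1 (45), 2 (1006) and 4 (34) and normal 5 (267).

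Of 78 list calls, 9 held with an estimated correlation and fry made 33. With single cases left out, 6 of 12 calls were lost at least once for I and II. So were 6 of 9 for I and III and 9 of 17 for II and III. Against normal, 0 of 8 were lost for LMS, 1 of 10 for I, 3 of 13 for II and 5 of 9 for III. In the order above, quantile normalization lost 3, 5, 4, 0, 1, 2 and 1 calls. Leaving out both doubtful cases lost 1, 5, 5, 0, 1, 0 and 1. Lists changed direction only against subtype III. Sex steroid genes (I and III) turned to 0.110 without both doubtful cases, and with single cases left out lay between −1.23 and 0.0251 (without III replicate 1); immediate early genes lay between −0.35 and 0.16 (without III replicate 4). HOX genes (II and III) turned to 0.00375 without III replicate 1, alone or with I replicate 7, and with single cases left out lay between −0.73 and that value. Fry, which does not compare a list with other genes, had the other direction for proliferation (shift −0.25) and immediate early genes (−0.18) between I and III and for adipocyte (−0.45), nerve (−0.39), HOX (−0.33) and interferon genes (−0.44) between II and III.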

Other observations

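The tests of the 2 score relations were chosen before their results were seen.

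The normal lung case held the surfactant genes SFTPC at 369 FPKM and SFTPB at 146 FPKM, and the skeletal muscle case held ACTA1, the skeletal actin, at 1620 FPKM, CKM, the muscle creatine kinase, at 462 FPKM and MYH7, a slow myosin heavy chain, at 289 FPKM. TOP2A was at 0.216 FPKM in the lung and 0.498 FPKM in the skeletal muscle, and CDKN2A at 0.110 and 0.0229 FPKM. Among the immediate early genes FOS stood at 77.4 FPKM in the lung and 88.2 FPKM in the skeletal muscle, beside 104.2 ± 80.0 FPKM (SD, n = 5) in normal smooth muscle. These cases are 1 each and were compared by no test.

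LMS cases with fewer smooth muscle transcripts might carry more proliferation transcripts or more matrix transcripts. Over the 17 LMS cases Pearson's r of the smooth muscle score was 0.0328 with the proliferation score (permutation p = 0.90, rho = 0.17 with permutation p = 0.52) and −0.18 with the matrix score (permutation p = 0.49, rho = −0.10 with permutation p = 0.70), with an adjusted p = 0.90 for both of the 2 relations. Without the 2 cases farthest from the median smooth muscle score r was −0.16 and −0.50. Within subtype I (n = 8) r was 0.60 (exact p = 0.093) and 0.72 (exact p = 0.057), and within subtype II (n = 6) −0.53 (exact p = 0.25) and 0.68 (exact p = 0.12). Without the 2 farthest cases these became 0.42 and −0.34 within subtype I, where the sign of the matrix relation turned and so rested on those cases, and −0.93 and 0.90 within subtype II. The written bound against each hypothesis, an adjusted p of 0.05 or more, was met, but r lay within its spread, so neither relation was shown and neither was excluded.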
